A study of Drosophila melanogaster with 6 samples.

How the data were processed

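The data are 6 simulated paired-end, unstranded RNA-seq libraries of Drosophila melanogaster S2 cells, 3 for condition C1 and 3 for condition C2. Per the labels, fragments had a mean length of 180 bp and an SD of 20 bp, and the design text names FlyBase transcripts as the source of the reads. Replicate variability was drawn from a negative binomial model fitted to real counts, per the series' design text. Reads were mapped with TopHat 1.3.1 and each library was assembled separately with Cufflinks 1.1.0, per the submitters' processing notes and the design text; a merged assembly was made with Cuffmerge. Cuffdiff, named in the same notes, has results that were not used here.

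The deposited FPKM values (fragments per kilobase of transcript, relative to the mapped fragments of the library) are attributes of the transcripts in each library's assembly, and the authors' normalisation is the one Cufflinks applied per library. Each value carries an interval in the same files, and its width gave the depth. Transcripts that held the full isoform fraction are called alone in their locus here. For these the square of 2 times the FPKM over the half-width of the interval came out whole within 0.02 for 99.96% to 100% of transcripts, and was read as a fragment count. With the stated mean fragment length these counts implied a normalisation to between 11633944 and 11635320 fragments in every library. For transcripts alone in their locus, the intervals cover counting error only. The fewest fragments behind a transcript alone in its locus were 8 to 10 per library. An FPKM of 0 here means that the library lists no such transcript. Fragments too few to assemble may exist, and since the isoform fractions sum to under 0.9 in 19.4% of loci, rows left out of the files cannot be excluded. The lowest isoform fraction in each library was 0.100 or 0.101. Over the 6 libraries 39 transcripts were under 180 bp, shorter than the mean fragment.

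Library transcripts were joined to the merged assembly of 26499 transcripts and 14764 genes by chromosome, strand and intron chain, which placed between 8525 and 8822 per library. The others went to the gene with the most shared exonic bases on a compatible strand. Between 1 and 2 transcripts per library lay in no merged gene and were left out of the comparisons. The FPKM of a gene is the sum over its transcripts in a library. Overlapping genes share fragments in unstranded data, and 382 loci of the merged assembly hold more than 1 gene, so genes in such loci are uncertain. Genome build and coordinates are those of the deposited assembly; the build is not given in the sources used here. Of 19452 reference transcripts found by identifier in a BDGP6 annotation, 3.70% had the same position, so that annotation was not used for coordinates. Annotated transcripts per gene were counted from the merged assembly.

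Genes and multi-exon transcripts were tested when assembled in at least 3 of 6 libraries with a mean FPKM of at least 1. Values were log2(FPKM + 1) and were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), C2 against C1, with Benjamini-Hochberg adjustment over all tested features. Isoform proportions were tested with diffSplice and Simes' method. The 20 gene lists and the rule for named genes were fixed before the data were examined, and 19 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Library-level values were compared with exact two-sided permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. Differences of fragment counts between replicates of a group were far above sampling noise (mean chi-square per transcript of 6.03 to 6.44 with 1 degree of freedom, over 1946 transcripts), so no library was a copy of another.

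The rule for named genes took the 10 largest rises among genes assembled in all 6 libraries with groups that did not overlap, the 8 called genes with the highest mean FPKM, and the 6 largest falls under the same conditions. It also took up to 4 called genes from each list that passed and up to 2 from each other list, the 4 genes with the smallest p for isoform proportions, and 9 reference genes, namely Act5C, Act42A, alphaTub84B, betaTub56D, RpL32, Ef1alpha48D, Gapdh2, Tbp and regucalcin. Genes named beyond it are said to be so.

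The fit was tested on simulated FPKM of 6802 genes with the residual spread of the real ones. Of 50 genes raised 3-fold 92% were recovered, of 50 raised 2-fold 76%, of 50 raised 1.5-fold 52%, and of 50 lowered to a fold of 0.5 64%; 8 of 6602 unchanged genes were called. In a simulation of isoform proportions on 963 genes, 91 of 100 genes with 1 isoform raised 3-fold were recovered and 15 others were called. These false calls were a larger share of the calls than the adjusted p threshold of 0.05 allows. Both simulations held only features assembled in all 6 libraries, so they say nothing on calls that rest on a value of 0 in a group.

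Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, scaling by the median ratio, quantile normalisation, other filters, no intensity trend, a test against a fold of 1.2, a replicate block, other ways of joining transcripts to genes, and leaving out each library in turn. Leaving out transcripts under 200 bp, and counting among the calls only features assembled in all 6 libraries, were added after seeing the data.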

Results

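The libraries are simulated: paired-end, unstranded RNA-seq reads were drawn in silico from transcript levels measured in Drosophila melanogaster S2 cells, an embryonic line with hemocyte-like properties. Condition C1 has 3 replicates at those levels. Condition C2 has 3 replicates in which the leading isoform of 300 genes was stated to be raised 3-fold, with no gene stated to be lowered. The values are FPKM of transcripts that Cufflinks assembled from each library. Each library held between 10517 and 10860 transcripts. The deposited intervals implied a normalisation to between 11633944 and 11635320 fragments per library, and the least covered transcript that was alone in its locus rested on 8 to 10 fragments. The replicates are random draws around shared levels, so the p-values measure simulated spread between draws and not spread between cultures. The comparison of C2 with C1 asks which genes, transcripts and isoform proportions differ when the raised set is embedded in an otherwise shared transcriptome.

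Among the genes higher in C2, Dredd, the caspase of the Imd immune pathway, had the largest change of those assembled in all 6 libraries, from 8.31 ± 0.902 to 31.9 ± 0.820 FPKM (SD, n = 3 each). CG4389 and CG8331 rose from 74.6 ± 6.16 to 239.6 ± 17.7 FPKM and from 128.2 ± 12.4 to 399 ± 20.5 FPKM. As ratios of mean FPKM, the rises of Dredd, CG4389 and CG8331 were 3.83-, 3.21- and 3.12-fold. These lie above the stated 3-fold rise of 1 isoform, and the cause was not tested. The transcription factor gene crc, the fly counterpart of ATF4, rose 2.60-fold from 407 ± 6.43 to 1056 ± 16.9 FPKM, and scf rose 2.51-fold from 398 ± 24.7 to 999.96 ± 18.9 FPKM. Pgi, which encodes the glycolytic enzyme phosphoglucose isomerase, rose 2.55-fold. In the whole comparison 231 of 7272 tested genes were higher in C2 and 31 were lower (limma on log2(FPKM + 1), two-sided, Benjamini-Hochberg adjusted p under 0.05).

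The log2 fold change of Dredd was 1.82 (SE 0.09, adjusted p = 7.98e-05 by limma), and that of CG4389 was 1.67 (SE 0.08). CG8331 changed by 1.64 (SE 0.08) on the log2 scale, crc by 1.38 (SE 0.03) and scf by 1.33 (SE 0.05). The tyrosine kinase gene Csk rose by 1.40 (SE 0.20) from 79.8 ± 25.2 FPKM. CG12360 rose 2.48-fold from 46.3 ± 1.52 FPKM, and the diacylglycerol kinase gene Dgkepsilon 2.45-fold from 198 ± 6.80 FPKM. Rox8, which encodes an RNA-binding protein, changed by 1.27 (SE 0.24) with an adjusted p of 0.0424 by limma, and its C1 values were 66.6, 34.8 and 35.2 FPKM. The Rox8 call was lost in 5 of the 6 fits that left out a library, with adjusted p between 0.127 and 0.151. With only transcripts whose intron chain matched the merged assembly, the change of Dredd was 0.37 (adjusted p = 0.184) and that of Csk 0.93 (adjusted p = 0.0935). In the coordinates of the deposited assembly, whose genome build is not given in the sources used here, Dredd lies on chromosome X from 523816 to 529760 on the minus strand with 3 annotated transcripts. On the same coordinates crc lies on 2L from 21310854 to 21319536, Pgi on 2R from 4798407 to 4801631, and scf on 3L from 1298618 to 1300389.

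**Figure D1:**
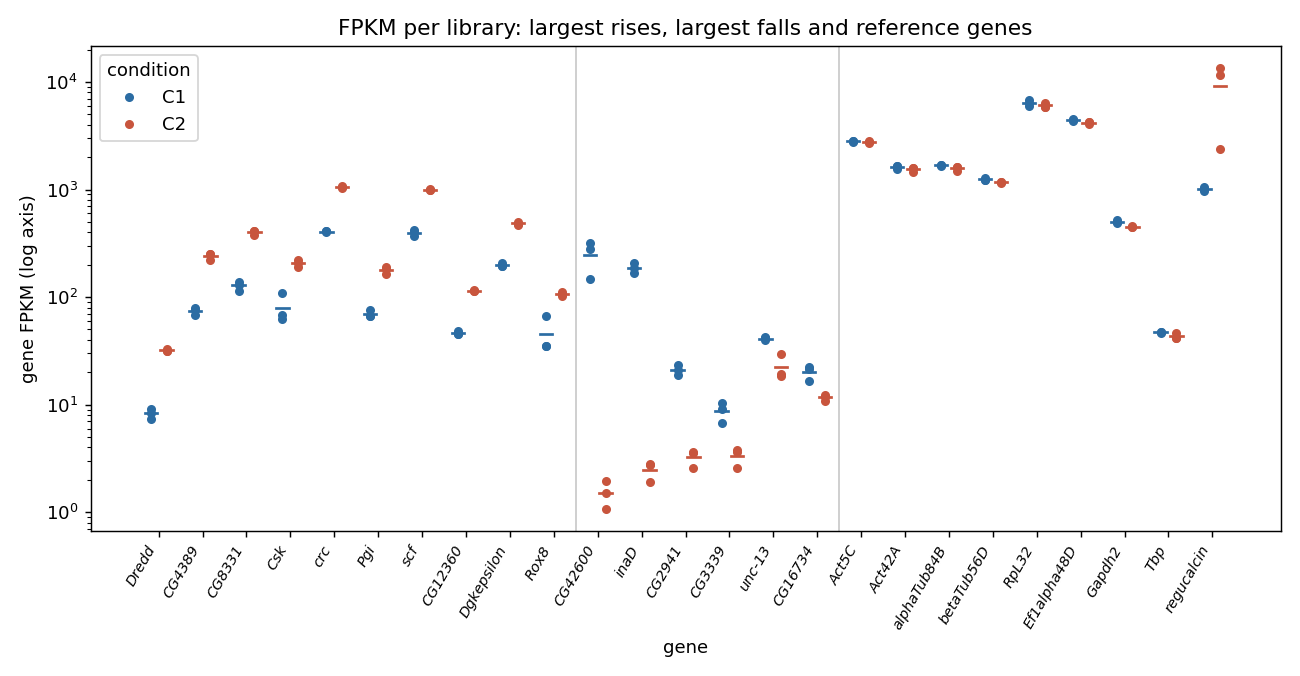
Gene FPKM on a log axis in each of the 3 C1 and 3 C2 libraries (points, with a bar at the group mean) for the 10 largest rises, the 6 largest falls and the 9 reference genes. In the first block every C2 point lies above every C1 point, with Dredd at 8.31 FPKM in C1 and 31.9 FPKM in C2, and the C2 points of regucalcin are spread from 2366 to 13511 FPKM.

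The fixed gene groups held at most 7 called members each, and no group passed the set test against other genes. Of 12 tested glycolysis genes, 3 rose and 9 did not pass: Pgi, Pglym78 (65.9 ± 2.15 to 130.2 ± 1.77 FPKM) and the aldolase gene Ald. Of 22 oxidative phosphorylation genes, 2 rose: ATPsyn-gamma, a subunit of the ATP synthase, from 633 ± 25.9 to 1350.1 ± 20.1 FPKM, and SdhA, a subunit of succinate dehydrogenase, from 103.1 ± 3.05 to 189.7 ± 7.54 FPKM. Of 16 vacuolar ATPase genes, Vha68-2 rose 2.37-fold, VhaSFD rose from 81.9 to 182.6 FPKM and Vha44 fell. Vha44 was listed at 29.2, 28.1 and 56.4 FPKM in C1 and at 0 in every C2 library. Ald, VhaSFD, eIF-4E and eIF-4a are outside the fixed rule for named genes and were chosen after their values were seen.

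Of 29 translation factor genes, 3 rose and 1 fell: eRF1, the termination factor, rose 1.62-fold from 181 ± 5.55 FPKM, eIF4E-6 rose 1.57-fold from 35.8 ± 3.61 FPKM, eIF-4E rose from 232 to 314 FPKM, and eIF-4a fell from 3085 to 2781 FPKM. The eIF-4a call was lost when each library was scaled by its median ratio (log2 change -0.15, SE 0.03, before and -0.08, SE 0.03, after; adjusted p = 0.413 by limma). Among 27 Toll and Imd pathway genes, Dredd and dl rose; dl, the NF-kappaB factor dorsal, went from 78.2 ± 2.40 to 106.3 ± 5.70 FPKM. With intron chain matches only, dl changed by -0.05 (adjusted p = 0.788). Of 16 JAK/STAT and JNK pathway genes, kay, the fly Fos gene, rose 1.86-fold from 192.5 ± 20.8 FPKM. Of 24 chaperone genes, Droj2 rose 1.68-fold from 270.04 ± 3.95 FPKM. Of 12 germline markers, mael rose from 18.9 ± 0.890 to 31.4 ± 2.06 FPKM and exu from 31.1 ± 1.45 to 46.9 ± 2.52 FPKM.

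No member passed among 63 mitochondrial ribosomal protein genes, 26 proteasome genes, 20 tRNA synthetase genes, 23 splicing factor genes, 30 cell cycle genes or 16 ecdysone response genes. The same held for 21 hemocyte markers, 13 neuron markers, 16 muscle markers, 6 fat body markers and 2 gut markers. Adjusted over the list alone, the calls were 2 higher and 25 lower for cytoplasmic ribosomal proteins, 3 and 1 for glycolysis, 2 and 2 for the vacuolar ATPase, and 3 and 4 for translation factors. In the remaining lists, the counts adjusted over the list alone equalled those over all genes. The median log2 change of the cytoplasmic ribosomal proteins was -0.08, near the -0.07 of all tested genes. By limma's camera with a preset correlation, 0 of 19 lists of sufficient size passed, 3 had an unadjusted p under 0.05, and 0 passed with an estimated correlation. By fry, which tests the genes of a list together and does not set them against other genes, 9 lists passed, 4 up and 5 down. The 4 were oxidative phosphorylation, glycolysis, vacuolar ATPase and germline markers, although their median log2 changes were -0.08, -0.08, -0.08 and 0.00, the means of oxidative phosphorylation and vacuolar ATPase were -0.20 and -0.25, and 2, 3, 2 and 2 members were called higher. The 5 were cytoplasmic ribosomal proteins, proteasome, splicing factors, cell cycle and hemocyte markers. Their median log2 changes were -0.08, -0.09, -0.12, -0.09 and -0.11, beside -0.07 over all tested genes. The smallest camera value was that of the cytoplasmic ribosomal proteins, with an adjusted p of 0.0587 (0.319 with an estimated correlation).

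Of the 8 most abundant called genes, 7 encode cytoplasmic ribosomal proteins, and of the 80 tested genes of that list 2 rose and 5 fell. RpL31 rose from 5206 ± 203 to 11182 ± 430.3 FPKM and RpS9 from 4937 ± 72.1 to 10288 ± 149 FPKM, log2 changes of 1.10 (SE 0.04) and 1.06 (SE 0.02). RpS3, RpL7, RpL18, RpL9 and RpL4 fell by 0.13, 0.13, 0.12, 0.19 and 0.14 on the log2 scale, with adjusted p between 0.0128 and 0.0460 by limma, and all 5 calls were lost after scaling by the median ratio. With 1 library left out at a time, the calls of RpL18 and RpL4 were lost in all 6 fits, those of RpS3 and RpL7 in 5 and that of RpL9 in 2. RpL9, for example, went from 3798 ± 91.2 to 3335 ± 66.1 FPKM, and its change was -0.12 (adjusted p = 0.123) after that scaling. The other 73 tested genes of this list did not pass. The median change of all 7272 tested genes was -0.07 on the log2 scale and -0.01 after scaling. CG32521 rose from 8116 ± 202 to 19665 ± 2829 FPKM, a value carried by a piece of 130 to 136 bp with 91 to 203 fragments. The log2 change of CG32521 was 1.27 (SE 0.10), and with quantile normalisation it was larger but more spread, at 1.96 (SE 0.44), and the call was lost (adjusted p = 0.0874). Without single-exon transcripts its change was -2.88 (adjusted p = 0.471). The short piece was listed with 1 exon in C2 replicates 1 and 3 and with 2 exons in the other libraries, so this setting removed it from that pair alone. With transcripts under 200 bp left out, an alternative chosen after seeing the data, its change was 1.17 (adjusted p = 3.21e-05).

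Genes lower in C2 ranged from large losses to small shifts. CG42600 went from 248 ± 90.2 to 1.51 ± 0.444 FPKM and inaD, which encodes a scaffold protein of photoreceptor signalling, from 187 ± 20.2 to 2.48 ± 0.491 FPKM. CG42600 lies on 2R from 5475458 to 5485943 on the minus strand, and its span overlaps that of RpL31, which ends at 5475505 on the plus strand. The reads carry no strand, so unspliced fragments within that overlap cannot be assigned by strand. Whether this bears on the fall of CG42600 was not tested. CG2941 fell from 21.0 ± 2.25 to 3.24 ± 0.562 FPKM, and with intron chain matches only its change was 2.08 in the other direction (adjusted p = 0.0302). CG3339 fell by 1.16 (SE 0.20) on the log2 scale and CG16734 by 0.74 (SE 0.13), the latter by 0.12 (adjusted p = 0.788) with intron chain matches only. The synaptic gene unc-13 fell by 0.88 (SE 0.17) from 41.2 ± 1.48 FPKM, a call lost after scaling with a change of similar size, -0.81 (SE 0.17, adjusted p = 0.0659). Its change was -0.17 (adjusted p = 0.507) with intron chain matches only and -0.01 (adjusted p = 0.984) without single-exon transcripts. The calls of CG3339, CG16734 and unc-13 were each lost in 5 of the 6 fits that left out a library.

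Of the 31 lower genes, 10 were listed at 0 in every C2 library, and 21 were assembled in all 6 libraries. The number of lower genes was 19 after scaling by the median ratio and 13 when tested against a fold of 1.2 with limma treat. It was 17, 16 and 12 without C1 replicate 1, 2 and 3. There the 10 genes at 0 in C2 no longer reach 3 libraries and were not tested, and of the 21 assembled in all 6 libraries 13, 14 and 14 lost the call. For all 231 higher and 31 lower genes the values of the groups did not overlap, and 21.0% of all tested genes had no overlap, against 10% by chance for 3 against 3.

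Of the 9 reference genes, 8 differed by small amounts that did not pass. Act5C was at 2810 ± 38.6 FPKM in C1 and 2788 ± 61.2 in C2, Act42A at 1614 ± 50.7 and 1547.5 ± 70.7, and alphaTub84B at 1685 ± 12.6 and 1577 ± 66.9. Values for betaTub56D were 1241 ± 24.8 and 1166 ± 7.84 FPKM, for Ef1alpha48D 4455 ± 107 and 4196 ± 117, and for RpL32 6374 ± 384 and 6066 ± 272. Gapdh2 was at 503 ± 13.1 and 453 ± 7.97 FPKM, and Tbp, the TATA-binding protein gene, at 47.2 ± 0.710 and 43.2 ± 2.91. Adjusted p-values of these 8 genes by limma lay between 0.115 and 0.881, and the log2 differences of Act5C and Act42A changed sign, to 0.06 and 0.01, after scaling. regucalcin, a gene for a calcium-binding protein, did not pass at the gene level (log2 change 2.84, SE 0.63, adjusted p = 0.0854). Its C2 values were 2366, 13511 and 11685 FPKM, and in the latter pair a single-exon piece of 98 bp carried 11200 and 9356 FPKM from 18 and 15 fragments. The change of regucalcin passed when assembly in all 6 libraries was required (2.84, adjusted p = 0.0480) and without C2 replicate 1 (3.64, adjusted p = 2.13e-05). It was 1.21 with intron chain matches only (adjusted p = 1.64e-05), without single-exon transcripts (adjusted p = 9.92e-06) and, an alternative chosen after seeing the data, with transcripts under 200 bp left out (adjusted p = 8.96e-06).

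At the level of single transcripts, regucalcin had 1 isoform that rose and another that was not listed in C2. Its main isoform FBtr0073576 rose from 848 ± 29.9 to 2335 ± 27.9 FPKM (log2 change 1.46, SE 0.03, adjusted p = 2.42e-05 by limma), while FBtr0073578 went from 159 ± 11.8 FPKM to a listed value of 0 in all C2 libraries. Among 9267 multi-exon transcripts tested, 225 were higher in C2 and 138 were lower. Of the higher ones 166 were assembled in all 6 libraries, with a median log2 change of 1.46 (quartiles 1.24 and 1.63), beside 1.58 for the stated 3-fold rise. The 225 higher genes assembled in all 6 libraries had a median fold of 1.80, and the median log2 change of all 231 higher genes was 0.85 (quartiles 0.67 and 1.02). The log2 changes are on the log2(FPKM + 1) scale, which understates changes of low transcripts, and the fold of 1.80 is a ratio of mean FPKM.

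**Figure D2:**
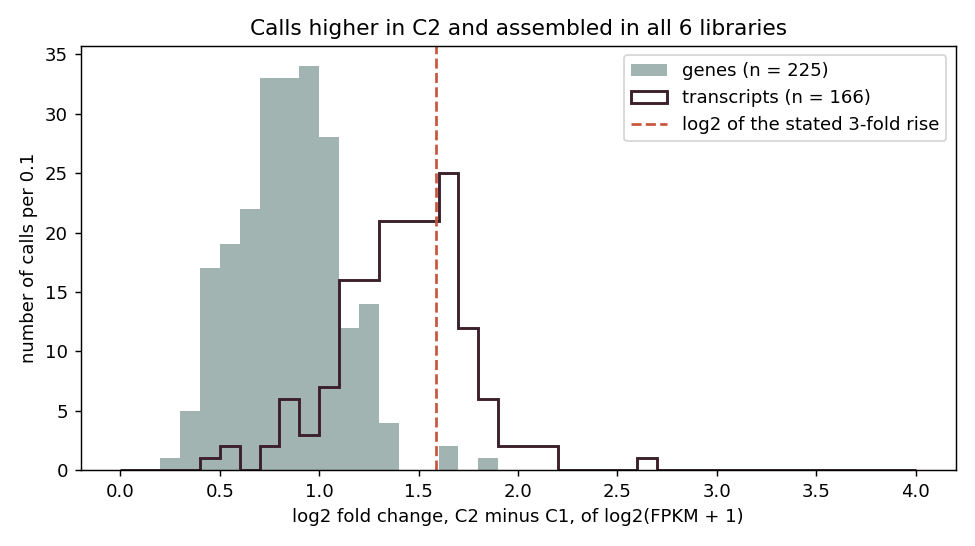
Histogram of log2 fold changes (C2 minus C1, on log2(FPKM + 1)) for the 225 genes and the 166 transcripts that were higher in C2 and assembled in all 6 libraries, in steps of 0.1, with a dashed line at 1.58 for the stated 3-fold rise. The transcripts are centred on a median of 1.46 and the genes lie lower, with quartiles of 0.67 and 1.02 over all higher genes.

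The 225 higher transcripts belonged to 215 genes, of which 170 were also higher at the gene level, and 276 genes were higher at either level. Of the 138 lower transcripts, 125 were listed at 0 in every C2 library, and 93 lay in a gene with a higher call. The count of lower transcripts depended on such losses: it was 13 among those assembled in all 6 libraries and 9 when that was required before testing. It was 69 at a mean FPKM of at least 10. Without C1 replicate 1, 2 or 3 it was 3, 1 and 4: the 125 transcripts at 0 in C2 are then in too few libraries to be tested, and of the 13 others 12, 13 and 13 lost the call. Of the 225 higher transcripts, 59 were listed at 0 in every C1 library, as were 6 of the 231 higher genes. The count of higher transcripts was 150, 147 and 149 without C2 replicate 1, 2 and 3, where the 59 are in too few libraries to be tested.

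Proportions of the listed isoforms differed in 123 of 1821 genes with at least 2 tested transcripts (limma diffSplice, Simes, adjusted p under 0.05), and 100 of these had a higher gene or transcript call. A listed value of 0 means only that the assembly of the library held no such chain. By the stated design the leading isoform of 300 genes rose 3-fold, which changes proportions, and nothing was stated to be lowered. A listed fall to 0 in C2, or a listed rise from 0 in C1, is not a change that the design states. Such listings therefore point to the assembly and not to the isoform levels. How the 123 genes divide between these sources was not tested. In CG3164 the isoforms FBtr0100379 and FBtr0078155, at 81.7 ± 3.20 and 55.5 ± 2.99 FPKM in C1, were listed at 0 in C2, where FBtr0078154 and FBtr0078153 stood at 197 ± 8.52 and 61.2 ± 1.73 FPKM (adjusted p = 6.32e-26). In RpS9 a chain of 4 exons, FBtr0076423, held all the listed FPKM of the gene in C1, and a chain of 3 exons, FBtr0076425, held all of it in C2 (adjusted p = 5.76e-18). In CG7546 the isoform FBtr0076792 rose from 36.7 ± 1.27 to 85.4 ± 2.74 FPKM. FBtr0076791, at 24.1 ± 0.873 FPKM in C1, was listed at 0 in C2, and FBtr0290025, at 30.8 ± 1.40 FPKM in C2, was listed at 0 in C1. G-salpha60A, the gene of the stimulatory G protein subunit, kept a similar total of 51.5 ± 0.671 and 46.8 ± 1.59 FPKM while 2 of its 4 tested isoforms were listed at 0 in C2 and another was listed at 0 in C1. The number of genes with changed proportions was 73 among transcripts assembled in all 6 libraries and 74 at a mean FPKM of at least 10. It was 63, 70 and 63 without C1 replicate 1, 2 and 3.

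**Figure D3:**
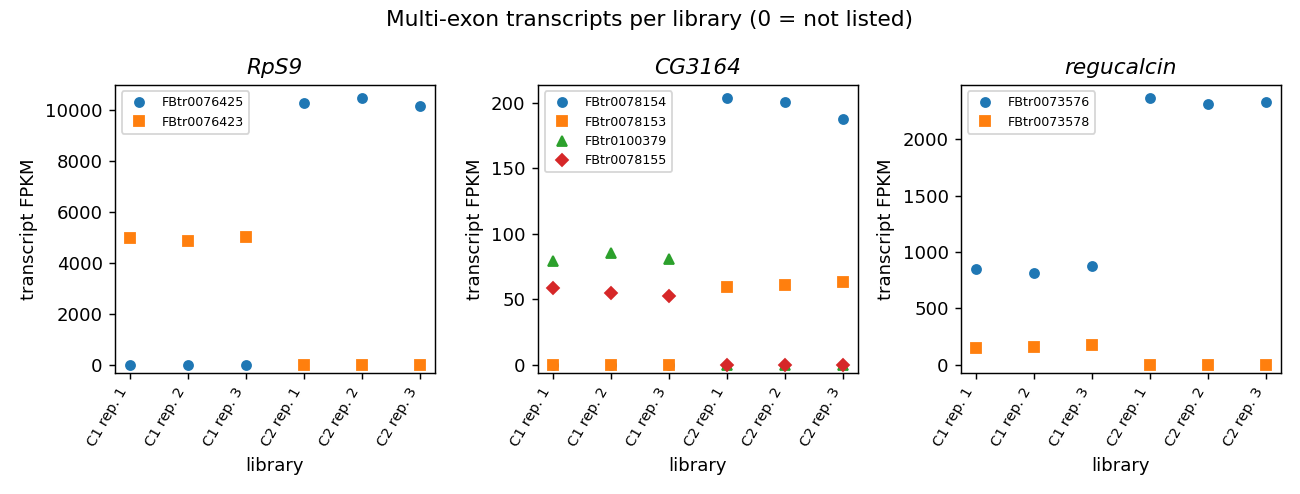
FPKM of each tested multi-exon transcript of RpS9, CG3164 and regucalcin in the 6 libraries, with 0 for a transcript that was not listed. In RpS9 the transcript at 4937 FPKM on average in C1 is at 0 in C2 and another stands at 10288 FPKM there.

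The assemblies of C2 were smaller. C1 libraries held 10848 ± 11.2 transcripts and C2 libraries 10547 ± 26.4 (SD, n = 3 each), a difference of -300.3 with an exact two-sided permutation p of 0.1, the smallest that 20 arrangements of 3 against 3 allow. Genes with an assembled transcript numbered 7347 ± 5.03 in C1 and 7287 ± 20.5 in C2. The share of multi-exon transcripts with the intron chain of a reference transcript was 82.9% ± 0.219 in C1 and 83.1% ± 0.299 in C2, which did not differ beyond the spread (exact permutation p = 0.3, n = 3 each).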

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

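The tests of the FPKM values above 10000 were chosen after those values were seen. Transcripts in no merged gene summed to 8.79, 8.38 and 8.60 FPKM in the C1 libraries and to 4.56 and 8.06 in C2 replicates 1 and 2, but to 1519798 in C2 replicate 3, a signal outside the gene comparisons and above the level of C1. It comes from a single-exon transcript of 75 bp on 3R from 27780700 to 27780774, with 1519791 FPKM from 8 fragments.

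The wider pattern is that 5 values above 10000 FPKM rested on fewer than 300 fragments, in CG32521, regucalcin and this transcript, all in C2. The median of the fragments behind them was 0.544 times that of all transcripts alone in their locus, and the longest of the 5 transcripts had 135 bp. Both values are fixed by how the 5 were picked, since fewer than 300 fragments at that FPKM leave an effective length under 2.58 bp, so neither test decides between abundant RNA and transcripts shorter than the fragments. That bound does show that the 5 values arose from few fragments divided by a very short effective length, such as 8 fragments at 75 bp. Whether the RNA behind them was abundant stays open. The piece of CG32521 stood just under the bound in C1, at 7782 to 8191 FPKM, and values above 10000 FPKM in transcripts under 180 bp were not confined to C2: a piece of RpS19a had 365077 FPKM from 4473 fragments in C1 replicate 2 and 374060 FPKM from 4333 fragments in C2 replicate 1. No biological explanation was tested, since the libraries are simulated.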

How the results depend on the processing

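The alternatives with transcripts under 200 bp left out, and the counts limited to calls assembled in all 6 libraries, were chosen after seeing the data. The 231 higher genes ranged from 185 (fold of 1.2) to 242 (scaled) over the settings, and from 210 to 234 with a library left out; all 231 were also called after scaling. The 31 lower genes became 19 after scaling, 13 at a fold of 1.2, and 12 to 27 with a library left out. Of the 31, 8, 7 and 7 were kept without C1 replicate 1, 2 and 3, and 17, 15 and 17 without C2 replicate 1, 2 and 3. The 225 higher transcripts ranged from 147 to 255 with a library left out, and without a C2 library the 59 listed at 0 in C1 could not be tested. The 138 lower transcripts became 9 when assembly in all 6 libraries was required, 13 when only such calls were counted, 69 at a mean FPKM of at least 10, and 1 to 177 with a library left out. Without a C1 library the requirement of 3 libraries removed 125 of the 138 from testing, and 12 to 13 of the other 13 lost the call. Without C2 replicate 1, 2 and 3, 13, 13 and 9 of the same 13 lost it. Genes with changed isoform proportions, 123, went to 164 with a pseudocount of 5, to 73 with assembly in all 6 libraries and to 74 at a mean FPKM of at least 10, where 964 and 978 genes were tested, and to 63 to 126 with a library left out. Gene lists went from 0 to 1 with a pseudocount of 0.1, with a pseudocount of 5 and with no filter, to 5 with quantile normalisation and to 9 by fry, and to 0 to 1 with a library left out; the cause was not tested. The median log2 change of higher genes, 0.85, was 0.79 with a pseudocount of 5, 0.90 after scaling, 0.90 at a fold of 1.2, 0.87 with intron chain matches only, and 0.84 to 0.89 with a library left out. That of all tested genes, -0.07, was -0.0761 with a pseudocount of 0.1, -0.0612 with 5, -0.00586 after scaling and -0.0239 with quantile normalisation; scaling centres it by construction. The difference in assembled transcripts stayed between -309.2 and -279.0, and that in the reference share between 0.129 and 0.419 percentage points, neither of which a test of this size could pass. The filter on a lower confidence limit above 0 removed nothing.

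Replicate numbers did not pair the libraries: correlations of deviations between same-numbered libraries were 0.0145, -0.0549 and 0.0179. With a replicate block the counts were 211 higher and 16 lower genes, 177 higher and 108 lower transcripts, 103 genes with changed proportions and 0 lists, and the assembly difference was -300.3 with an exact sign-flip p of 0.25. Of 944 values for 48 named genes under the alternatives, 838 kept their direction and side of the threshold, 5 values of 3 reference genes changed sign without passing, 93 lost the call, 5 gained it and 3 reversed. The reversals were CG32521 at -2.88 without single-exon transcripts, and, with intron chain matches only, CG2941 at 2.08 and dl at -0.0472. For CG32521, that setting removed the short piece from C2 replicates 1 and 3 alone, where it was listed with 1 exon. The cause of the CG2941 and dl reversals was not tested. Spread was larger in low genes: the median within-group SD of log2 values was 0.55 for genes with a mean of 1 to 3 FPKM and 0.04 above 1000 FPKM. Whether depth was the cause was not tested.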

Other observations

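The tests of overlap with raised genes and of library share for the lower calls were chosen after the results were seen. So was that of genes with at most 1 annotated transcript. The values by 3 or more annotated transcripts, at 30 FPKM and among genes with at least 2 tested transcripts were also chosen then. Higher calls were spread over the chromosome arms, from 2.61% of tested genes on 3R to 3.66% on 2R, with 2 of 72 genes on chromosome 4. They were not spread over genes by number of annotated transcripts. Of 1433 tested genes with 3 or more annotated transcripts 14.7% were higher in C2, and of 5839 with fewer 0.343%. With 2 or more transcripts the odds ratio against other tested genes was 28.1 (Fisher's exact p = 1.59e-73). A bound of at least 30 FPKM on the mean leaves out low genes with their larger spread. Within it, 25.5% of genes with 3 transcripts and 0.492% of those with at most 1 were higher. A hypothesis is that the raised genes may have been drawn from genes with several isoforms and not from all genes. The files used here do not list the raised genes, so it remains open.

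The median log2 change of higher genes, 0.85, lay below 1.58. A pseudocount effect is argued against by 0.849 at a pseudocount of 0.1, and a smaller library share of every gene by 0.903 after scaling, both far below 1.58. The change fell with the number of annotated transcripts over the 231 genes (Spearman rho -0.569, permutation p = 2e-05, the smallest that 100000 permutations can give, over genes that are not independent replicates). Among genes with several transcripts this is consistent with isoforms that were not raised diluting the gene total, the median of raised transcripts being 1.46. Such dilution is argued against for the 7 higher genes with at most 1 annotated transcript that were assembled in all 6 libraries. Their median was 1.00 and their highest value 1.33, and the cause there stays open.

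Lower transcripts lay mostly in genes with a higher call. Of transcripts not called higher, 19.8% were lower in such genes and 0.525% elsewhere (odds ratio 46.9, Fisher's exact p = 2.04e-88, and 41.5 among genes with at least 2 tested transcripts). This argues against lowering spread evenly over loci. A gene where assembly listed another chain in C2 holds a higher and a lower call by construction, as RpS9 and G-salpha60A do. Of the 225 higher transcripts, 59 were at 0 in C1. The odds ratios count such exchanges, so they do not decide whether lowering depended on a raised isoform. A smaller library share would act at every locus. For the lower transcripts at 0 in C2 the odds ratio was 51.9 among genes with at least 2 tested transcripts. Such exchanges add to it, so it does not decide. The 138 lower transcripts, 125 of them at 0 in C2, had a median log2 change of -4.01, beside -0.07 over all tested transcripts. That size argues against a smaller share for those at 0. For 3 of the 13 lower transcripts assembled in all 6 libraries (23.1%) it is argued against by a call that passed after scaling. The 10 calls that ended had a median that went from -0.25 to -0.18 (median SE 0.04 before and after). Scaling left 72.8% of that median fall, a value between the bounds set for this test. These 10 were picked by their falls, which can leave part of a fall after scaling, so the part of a smaller share stays open. A filter on minor isoforms was expected to leave at least 80% of all lower transcripts under 0.1 times the highest overlapping C2 transcript, and 19.6% were (27 transcripts, all listed at 0 in C2), which argues against it as the cause of the whole set. Its part in the set stays open by 2 other measures, chosen after the results were seen: at their C1 level 34.1% would hold under 0.1 of the FPKM on their exons in C2, and 57.2%, against 19.7% of transcripts without a call, had a C1 fraction under 0.25 (which reaches 0.1 if the rest rises 3-fold), although deposited fractions sum to under 0.9 in 19.4% of loci, so they may not refer to the locus alone. Of the drop of 300.3 transcripts per library, 51.8% lay in genes with a higher call, a value between the bounds set beforehand, so its part in that drop cannot be told apart from other losses, and how assembly chose between isoforms, as in RpS9, stays open.

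Of the 31 lower genes, 12 spanned part of a gene with a higher call, against 0.756% of other tested genes (odds ratio 82.9, Fisher's exact p = 1.62e-17). CG9205 beside trio, CG4045 beside CG4199 and cav beside twin are examples chosen after their values were seen, at 151, 40.2 and 11.7 FPKM in C1 and listed at 0 in C2. No C2 transcript overlapped the exons of the tested transcript of CG9205, that of cav was overlapped at 2.01 FPKM at most, and that of CG4045 by a transcript of 578 FPKM on its own strand, so the cause of these losses stays open. A smaller library share is argued against for the 10 genes at 0 in C2, of which 9 spanned part of such a gene (odds ratio 1181), and for 9 of the 21 assembled in all 6 libraries (42.9%), which passed after scaling with a median of -0.67, from -0.74. The 12 calls that ended, the 5 ribosomal protein genes among them, had a median that went from -0.21 to -0.14 (median SE 0.04 before and after). Their largest fall went from -0.88 to -0.81 and their smallest from -0.12 to -0.05. Scaling left 66.9% of the median fall, a value between the bounds set for this test. These 12 were picked by their falls, which can leave part of a fall after scaling, so the test does not decide. The part of a smaller library share in their falls stays open.

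The median index of dispersion of fragments between replicates was 5.37 in C2 and 5.51 in C1, where counting alone gives about 1; the replicates were drawn from a negative binomial model, so the design fixes an index above 1 and the test decides nothing. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 231 higher and 31 lower genes, 225 higher and 138 lower transcripts, 123 genes with changed proportions and 0 lists. The highest of the other splits, taking the larger direction, gave 6 genes, 38 transcripts, 30 genes with changed proportions and 0 lists. For the first 5 counts 1 of the 10 splits, the real one, gave as many, and for lists all 10 did.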
